A study of Mus musculus with 18 samples.

How the data were processed

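Gene expression was measured in whole ovaries of mice, wild type or knockout for Elavl2, at embryonic day 15.5 (E15.5), embryonic day 17.5 (E17.5) and postnatal day 0 (P0). The series holds 18 samples, 3 for each of the 6 combinations of stage and genotype, each on its own array. Groups and replicate numbers were taken from the labels. Per the labels' protocols, dissected gonads were kept in RNAlater, RNA was purified on RNeasy Mini columns, and Cy3-labelled cRNA was made with a 1-colour low-input amplification kit.

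The arrays were of the Agilent 4x44K mouse type, design 014868, with 1 channel each. The deposited scanner files hold, for each spot, a background-subtracted intensity made by the authors with Agilent Feature Extraction. The version was 10.7.3.1 per the file headers and 9.5 per the submitters' processing notes, and the difference is not settled in the sources used here. The deposited series matrix holds log2 values. Set against the scanner files, each of its columns equalled the log2 intensity plus 1 constant per array, with the 75th percentile at 9.62 on every array and medians from 6.17 to 6.46. The matrix was therefore scaled by array and its genes were not centred. A value in the matrix without a probe name (1 row) was not used.

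Spots of control probes and spots with an outlier mark (51 to 109 per array) were left out, and no spot was saturated. The intensity of each of 41174 non-control probes was put on the log2 scale and the array's own 75th percentile was subtracted. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 29203 probes. The share of probes well above background lay between 62.5% and 75.2% per array. The number of arrays, 3 per group, limits the precision of every value. Probe accessions were matched to a table of mouse RefSeq genes of assembly GRCm38.p6 for names only: 28223 probes were named that way, 1471 of them with a changed name, and 12951 kept the name in the file. Coordinates are those of the files, on build mm9. The probe with the highest mean over all arrays stood for a gene, giving 19299 genes.

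Differences were tested with limma 3.58.1 in R 4.3.3. A single linear model (lmFit and eBayes) over all 18 arrays had the 6 groups and the run as terms, which left 11 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The run (A or B) was read from the form of the deposited file names, and it matched the day of the scan. All E15.5 arrays and replicate 3 of each E17.5 group were of run A, and the other arrays of run B. The arrays sat on 7 slides. Where a group's signal was below background on all its arrays, a fold is given as a lower bound, the brighter group's mean against the lowest signal well above background or the dim probe's own signal, whichever was higher on each array. Replicate numbers were checked for pairing by the correlation across genes of the deviations of same-numbered arrays from their group means. At E17.5 every pair lay over 0.1 (0.12, 0.40 and 0.45), and replicate 3 there was of another run and slide, so the value with the replicate block is given beside that comparison.

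Before the data were examined, 28 gene lists were fixed, and 27 with at least 3 measured members were tested. The tests were camera with a preset correlation of 0.01 between genes, camera with an estimated correlation, and fry. The 12 genes with the largest rise and the 12 with the largest fall were eligible to be named in each comparison of genotypes. They had to be called, well above background in a group, without overlap between the groups, and to carry a symbol. The 6 largest each way were eligible in the other comparisons, as were up to 4 members of each list with the smallest adjusted p. Elavl2 is named in every comparison. The text prints part of these genes, picked after their values were seen, while the alternatives below were run on all of them, apart from a few that are not reported here.

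Tested on simulated data made from these arrays, with 67 genes changed by each fold, 1.5-fold changes were recovered in 47.8% of cases at E15.5, 49.3% at E17.5 and 41.8% at P0. For 2-fold changes the shares were 70.1%, 74.6% and 76.1%. False calls made up 3.4%, 5.77% and 4.2% of calls. That simulation held independent noise and no slide effect, so it says nothing of slides.

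The alternatives tried were normexp background correction with quantile normalization, quantile normalization, scaling by the array median, the series matrix values, no filter, a stricter filter, no run term, the mean of a gene's probes, a trended and robust moderation, array weights, a 2-fold threshold, the slide as a random block, only the stages compared, the replicate number as a block, and leaving out each array. Leaving out slide 3, using the E17.5 arrays of run B only, and the slide as a fixed block were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.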

Results

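Expression profiles of whole mouse ovaries were compared between wild type and Elavl2 knockout animals at 3 stages around birth: E15.5, E17.5 and P0. Elavl2 encodes an RNA-binding protein of the ELAV family. Each of the 6 groups held 3 samples, and 18 arrays were read in all. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples. Replicate arrays correlated with Pearson's r of 0.9649 to 0.9948 across genes, and no pair of replicates held an identical value for any gene. The arrays were spread over 2 runs and 7 slides, and at E15.5 and P0 all wild type arrays shared a slide that held no knockout array. Of the E17.5 arrays, only those of replicate 3, on slide 3, shared a slide across genotypes. Values are log2 signals relative to the array's 75th percentile, changes are knockout against wild type unless stated, and an error after ± is a standard error unless SD is written.

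Elavl2 itself was measured by 2 probes on chromosome 4, and the brighter, used for the gene, lay at 90918411 to 90918470 and the other at 90919418 to 90919477 (mm9). Its level was 2.11 ± 0.16 in wild type and 2.00 ± 0.12 in knockout (SD, n = 3 each) at E15.5. At E17.5 it was 3.51 ± 0.14 in wild type and 2.65 ± 0.41 in knockout (SD, n = 3 each), and at P0 4.52 ± 0.06 in wild type and 3.16 ± 0.20 in knockout (SD, n = 3 each). The log2 change was -0.11 (SE 0.12, adjusted p = 0.75) at E15.5, -0.87 (SE 0.12, adjusted p = 0.0045) at E17.5 and -1.36 (SE 0.12, adjusted p = 9.11e-06) at P0. The dimmer probe gave -0.45, -0.97 and -1.63 (SE 0.16 each) at the same stages. With the E17.5 arrays alone the call at E17.5 ended. Over the mean of the 3 stages Elavl2 fell by 0.78 on the log2 scale (SE 0.07, adjusted p = 2.45e-05). The sources used here do not give the deleted part of the gene. A probe outside that part checks nothing, so these values do not check the genotype labels. Of the genes named here, Cdkn2a, Tek, Jun and Elavl4 also lie on chromosome 4 within 20 Mb of Elavl2. In that stretch 15 genes were called at E15.5 against 2.9 expected (Fisher's exact test, p = 2.4e-07).

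**Figure D1:**
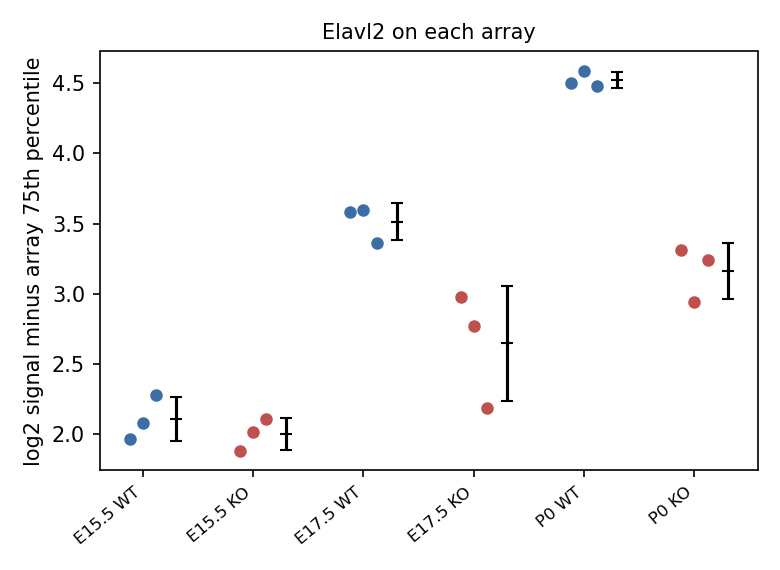
Elavl2 on each of the 18 arrays, as log2 signal minus the array's 75th percentile (vertical axis) by stage and genotype (horizontal axis). Points are arrays and black bars are the mean and SD of 3. The knockout arrays at P0 lie between 2.94 and 3.31, below the wild type arrays at 4.48 to 4.59, while the groups overlap at E15.5.

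At E15.5, when germ cells of the ovary are in meiotic prophase, 312 of 19299 genes were called between genotypes, 187 higher and 125 lower in knockout. The largest fitted rise was that of Fgf21, a metabolic hormone of the FGF family, which was at least 1.99-fold higher (adjusted p = 0.00112) and not well above background in wild type. Cdkn2a, which encodes the cell-cycle inhibitors p16 and ARF, rose by 2.60 (SE 0.32, adjusted p = 0.00602). The nuclear receptor gene Esrrb rose by 1.38 ± 0.26, the chloride channel gene Best2 by 2.32 ± 0.43 and the steroid dehydrogenase gene Hsd3b4 by 2.31 ± 0.47. Ghrl (ghrelin) rose by 1.72, the arginase gene Arg2 by 1.54 and the uroplakin gene Upk3a by 1.54. Among the genes that fell were the deubiquitinase gene Usp42 at -1.36 ± 0.15, the signalling ligand gene Wnt3 at -1.12 ± 0.23 and the coactivator gene Ppargc1a at -1.02 ± 0.22. The zinc finger gene Sall3 changed by -0.92 and Rufy2 by -0.91. The nephronectin gene Npnt gave -1.08, but its other probes went the other way.

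Of 27 gene lists, 4 were called at E15.5. Among 38 measured meiosis genes, 2 rose, 0 fell and 36 did not pass the test (median log2 change 0.25, camera adjusted p = 2.25e-06; adjusted p = 0.383 with an estimated correlation). Hormad2, a chromosome axis gene, rose by 0.62 ± 0.10 and Terb2, a meiotic telomere gene, by 0.66 ± 0.12, whereas the synaptonemal complex gene Sycp1 gave -0.41 ± 0.10. Within that list 5 rose and 1 fell adjusted over the list alone. Among 18 primordial germ cell and pluripotency genes, 1 rose, 0 fell and 17 did not pass the test (median log2 change 0.44, camera adjusted p = 0.000498; adjusted p = 0.167 with an estimated correlation), the riser being Esrrb, while Lin28a gave 1.46 ± 0.48. Of 31 cell division genes, 1 rose, 0 fell and 30 did not pass the test (median log2 change 0.19, camera adjusted p = 7.53e-05; adjusted p = 0.984 with an estimated correlation), with the spindle checkpoint gene Bub1 at 0.44 ± 0.09 and the replication gene Cdc45 at 0.40 ± 0.09. Without knockout replicate 1 the cell division list had a median of 0.04 and its call ended (adjusted p = 0.76). On that array the list stood at 0.55, against 0.08 and 0.12 on the other knockout arrays, and the red cell list at 3.45 against 0.35 and 0.84. The TGF-beta and activin list moved down: of 25 genes, 0 rose, 1 fell and 24 did not pass the test (median log2 change -0.15, camera adjusted p = 7.53e-05; adjusted p = 0.167 with an estimated correlation), led by Id1, a target of BMP signalling, at -0.94 ± 0.14, with Id4 at -0.53 ± 0.14. The death receptor gene Tnfrsf10b rose by 1.24 (0.81 without knockout replicate 3) and the endothelial receptor gene Tek changed by -0.46, with another probe of it going the other way. The 47 oocyte growth and zona genes had a median change of 0.28, and none passed the test (camera adjusted p = 0.294).

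The count at E15.5 rested on the spread shared with the other stages: with the 6 arrays of E15.5 alone limma called 0 genes, with 2894 at an unadjusted p under 0.05, and with the slide as a random block 144. Leaving out a single array gave 23 genes without wild type replicate 2, 82 without wild type 3, 84 without wild type 1, 162, 188 and 471 without knockout 3, 2 and 1. The balance of rises and falls turned with slide 3 or single arrays: 73 were higher and 89 lower without knockout 3, 38 and 44 without wild type 3, and 99 and 160 without slide 3, where 135 of 259 genes were among the 312. Other splits of the 6 arrays called up to 9 lists, with adjusted p down to 2.78e-14 for cell division, 0.000346 for the pluripotency list, 0.00544 for meiosis and 0.00101 for TGF-beta.

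At E17.5, 801 genes were called, 257 higher and 544 lower in knockout. Genes of growing oocytes were among the falls. Nlrp14, an oocyte-specific NLR family gene, had a log2 change of -3.02 (SE 0.67, adjusted p = 0.0267), Oog1, an oocyte-specific gene, -2.78 ± 0.70, and Padi6, of the oocyte cytoplasmic lattices, -2.42 ± 0.54. The maternal-effect gene Nlrp5 fell by 2.39 and Tcl1 by 1.79. Th, encoding tyrosine hydroxylase, changed by -2.61 ± 0.55 and the kinase-like gene Camkv by -1.93 (SE 0.20, adjusted p = 0.00212). Cldn16, a tight junction gene, was at least 1.72-fold lower and Nlrp4a at least 2.13-fold lower (adjusted p = 0.00272 and 0.00382). Among the rises, the deubiquitinase gene Usp17lb was at least 3.04-fold higher (adjusted p = 0.00212) and its relative Usp17la rose by 2.04 ± 0.36. Zscan4c, of a telomere-associated family, was at least 2.17-fold higher (adjusted p = 0.00752). Stra8, which starts meiosis in response to retinoic acid, rose by 2.06 (SE 0.43, adjusted p = 0.02). The X-linked homeobox gene Esx1 rose by 1.95 (SE 0.22, adjusted p = 0.00212), the testis gene Tsga8 by 2.37 ± 0.44, the homeobox gene Dlx1 by 1.24 ± 0.27 while the laminin gene Lamc3 was at least 2.15-fold higher (adjusted p = 0.0406).

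The oocyte growth and zona list was the lowest at E17.5. Of its 47 measured genes, 0 rose, 10 fell and 37 did not pass the test (median log2 change -0.86, camera adjusted p = 1.31e-08; adjusted p = 0.609 with an estimated correlation), and 1 rose and 16 fell adjusted over the list alone. The falls included the nucleoplasmin gene Npm2 at -1.22 ± 0.22 and Zbed3 at -0.94 ± 0.15. Of 23 pan-germ cell genes, 2 rose, 1 fell and 20 did not pass the test (median log2 change -0.31, camera adjusted p = 0.0041; adjusted p = 0.684 with an estimated correlation): Tex101 and Tex13b rose by 0.53 and 0.72, and the piRNA pathway gene Rnf17 changed by -0.72. The oocyte transcription factor list also went down with no single gene called (median log2 change -0.31, camera adjusted p = 0.0478; adjusted p = 0.684 with an estimated correlation). Meiosis genes as a list were not called (median -0.02, camera adjusted p = 0.3): beside Stra8, Syce1 and Sycp1 of the synaptonemal complex changed by -0.72 and -0.40. Upward lists held few called genes each. The endothelial genes Sox18 and Erg rose by 0.41 and 0.31 (median log2 change 0.19, camera adjusted p = 0.0129; adjusted p = 0.609 with an estimated correlation). In the p53 and apoptosis list, 4 rose, 0 fell and 26 did not pass the test (median log2 change 0.14, camera adjusted p = 0.0321; adjusted p = 0.422 with an estimated correlation), with Sesn2 at 0.49 and Pmaip1, which encodes NOXA, at 0.77. In the immediate early and stress list 1 rose, 0 fell and 21 did not pass the test (median log2 change 0.29, camera adjusted p = 0.0041; adjusted p = 0.609 with an estimated correlation), the riser being the heme oxygenase gene Hmox1 at 0.73. The macrophage list held Cd68 at 0.54 (median log2 change 0.25, camera adjusted p = 0.012; adjusted p = 0.684 with an estimated correlation), and the hedgehog list was also called (median log2 change 0.18, camera adjusted p = 0.0288; adjusted p = 0.609 with an estimated correlation). Cell division genes (median log2 change 0.20, camera adjusted p = 0.012; adjusted p = 0.69 with an estimated correlation) and stroma genes (median log2 change 0.13, camera adjusted p = 0.0321; adjusted p = 0.69 with an estimated correlation) were called as lists with no single gene past limma's threshold. Red cell genes had a median of 1.88 with 0 of 16 called (camera adjusted p = 0.012; adjusted p = 0.69 with an estimated correlation). Their median change was 4.66 in run A and 0.40 in run B, so the amount of blood RNA differed between arrays beside each of these lists. Gdf9, an oocyte growth factor, and Id1 changed by -1.27 and -0.81.

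Within run A, where knockout and wild type replicate 3 shared slide 3, Elavl2 changed by -1.17 and the oocyte growth list by a median of -1.79. Within run B the values were -0.72 and -0.52, while the stroma list had medians of -0.04 in run A and 0.22 in run B. In run B the wild type arrays lay on slide 4 and the knockout arrays on slide 5 at this stage. Slide and genotype therefore cannot be told apart within run B. In runs A and B the medians were -0.55 and -0.13 for pan-germ cell, -0.60 and -0.12 for oocyte transcription factor, 0.37 and 0.10 for cell division and 0.56 and 0.14 for macrophage genes. They were 0.20 and 0.16 for endothelial, 0.19 and 0.20 for p53, 0.23 and 0.26 for immediate early and 0.13 and 0.24 for hedgehog genes. Across all genes the changes of the 2 runs correlated with r = 0.19; genes are not independent replicates. With the replicate number as a block, which takes up the run, 167 genes were called, 157 of them among the 801, and the 11 list calls held. Of the genes named, Elavl2, Usp17lb, Usp17la, Zscan4c, Esx1, Cldn16, Nlrp4a, Camkv, Rnf17, Zbed3, Sox18 and Id1 kept their call, and the others did not (adjusted p = 0.0508 for Sesn2 to 0.128 for Tex101). In runs A and B Nlrp14 gave -5.33 and -1.86, Gdf9 -2.34 and -0.74, and Lamc3, as fitted, 2.25 and 0.72, and without either replicate 3, which leaves run B, these 3 calls ended. In run B Oog1, Camkv and Th gave -2.09, -1.97 and -1.90, each a larger fall than that of Nlrp14. Dlx1 gave 0.79 without knockout 1. With the slide as a fixed block, the E17.5 contrast rested on slide 3 alone, knockout 3 against wild type 3, 1 array each. It is therefore not a check separate from run A. Its medians were 0.202 for endothelial, 0.191 for p53 and 0.13 for hedgehog genes. The stroma list turned to the other side of 0, at -0.055. The E17.5 arrays alone gave 1 called gene with limma, run B alone 154, and leaving out an array between 141 (without knockout 2) and 1032 (without knockout 1), with 154 without either replicate 3, 253 without wild type 1 and 367 without wild type 2. Scaling by the array median called 385 genes, 19.7% of them higher in knockout against 32.1%. Leaving out single arrays ended 9 of the 11 list calls. Without either replicate 3, the calls of pan-germ cell, oocyte transcription factor, macrophage, red cell and cell division genes ended, at the medians of run B. Without wild type 1, knockout 1 or knockout 2 the stroma list had medians of 0.09, 0.11 and 0.10 and the hedgehog list 0.14, 0.19 and 0.13, and neither was called. The p53 call ended without knockout 1 (median 0.11), and the endothelial and oocyte transcription factor calls without knockout 2 (0.12 and -0.24). Another split of the same arrays gave the oocyte growth list a camera adjusted p of 4.42e-19. Other splits also went as low for every other called list except p53, where the lowest was 0.0844. The lowest was 1.13e-10 for cell division, 1.45e-09 for red cell, 2.64e-08 for pan-germ cell and 1.21e-05 for macrophage genes. It was 5.52e-05 for oocyte transcription factor, 0.000531 for stroma, 0.000933 for immediate early, 0.00188 for endothelial and 0.0108 for hedgehog genes.

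At P0, around the time when primordial follicles form, 6651 genes were called, 3534 higher and 3117 lower in knockout. At a change of at least 2-fold, 1222 were called, 337 higher and 885 lower. Genes of the zona pellucida and of oocyte growth fell the most. Zp3, which encodes a coat protein of the egg, went from 2.94 ± 0.13 in wild type to -2.38 ± 0.55 in knockout (SD, n = 3 each), a log2 change of -5.32 (SE 0.42, adjusted p = 3.3e-06). Npm2 changed by -5.04 (SE 0.22, adjusted p = 8.74e-08), the maternal-effect gene Zar1 by -4.80 ± 0.36, and Padi6 and Nlrp14 by -4.44 ± 0.54 and -4.44 ± 0.67. The knockout arrays were not well above background for Astl, the egg protease ovastacin, which was at least 23.9-fold lower, for the oocyte-secreted protein gene Oosp1, at least 9.06-fold lower, or for the interferon-inducible gene Ifi207, at least 18.9-fold lower. Aspg, an asparaginase gene, changed by -4.55 ± 0.21 and Khdc1a, of a family with KH domains, by -4.48 ± 0.50. Among the rises, Stra8 went from -3.93 ± 0.31 in wild type to -0.66 ± 0.65 in knockout (SD, n = 3 each), a log2 change of 3.26 (SE 0.43, adjusted p = 0.000133). Esx1 rose by 3.03 (SE 0.22, adjusted p = 1.93e-06), Radx, a replication fork protein gene, by 2.48 ± 0.19 and the cytochrome P450 gene Cyp4b1 by 2.45 ± 0.27. The olfactory receptor gene Olfr206 was at least 3.23-fold higher, the receptor gene Gpr174 at least 4.46-fold higher, and Insm1, a neuroendocrine transcription factor gene, was at least 4.31-fold higher and Ctag2 at least 2.2-fold higher. Slc22a13, a transporter gene, rose by 2.85 ± 0.51. Nkx2-4 gave 3.04, but another probe of it went the other way.

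At P0 camera called the oocyte growth list down and the meiosis list up. Of 47 oocyte growth and zona genes, 2 rose, 38 fell and 7 did not pass the test (median log2 change -2.55, camera adjusted p = 4.51e-17; adjusted p = 0.477 with an estimated correlation), and 2 rose and 39 fell adjusted over the list alone. Rfpl4 and Gdf9 were among them at -2.90 ± 0.20 and -3.30 ± 0.27. Of 38 meiosis genes, 20 rose, 4 fell and 14 did not pass the test (median log2 change 0.34, camera adjusted p = 0.000808; adjusted p = 0.477 with an estimated correlation). The recombinase gene Dmc1 rose by 1.67 ± 0.20, the meiotic cohesin gene Stag3 by 1.30 ± 0.12 and Mei1 by 0.94 ± 0.11, while Kash5, which links telomeres to the nuclear envelope, changed by -1.01 ± 0.10. Pan-germ cell genes were not called as a list (median log2 change 0.11, camera adjusted p = 0.217): of 23, 7 rose, 1 fell and 15 did not pass the test, with Tex101 at 1.48, Tex19.1 at 1.06 and Dazl, a germ cell RNA-binding protein gene, at 0.86. Among 18 primordial germ cell and pluripotency genes, 2 rose, 7 fell and 9 did not pass the test (camera adjusted p = 0.0864), including Pou5f1 at -3.73 ± 0.44, Tfap2c at -2.91 ± 0.32 and Dppa5a at -1.52 ± 0.23. Tbpl2, an oocyte TATA-binding protein gene, changed by -3.87 ± 0.39. In the processing body and mRNA repression list, 3 rose, 7 fell and 25 did not pass the test (camera adjusted p = 0.408), with Patl2 at -1.5 and the decapping enzyme gene Dcp2 at 0.79. Of the other ELAV family genes, Elavl3 changed by -0.70, Elavl4 by 0.41 and Elavl1 by 0.32. Without knockout replicate 3 Elavl4 gave 0.26 and was not called (adjusted p = 0.148). The mean of the probes of Elavl1 gave -0.03, on the other side of 0. Of 20 genes of primordial follicle dormancy, 3 rose, 4 fell and 13 did not pass the test (camera adjusted p = 0.408), with Serpine2 at -0.75, the kit ligand gene Kitl at 0.48 and Tsc1, of the complex that restrains mTOR, at -1.20. The probes of Tsc1 disagreed, and with normexp correction it gave 0.145, on the other side of 0.

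**Figure D2:**
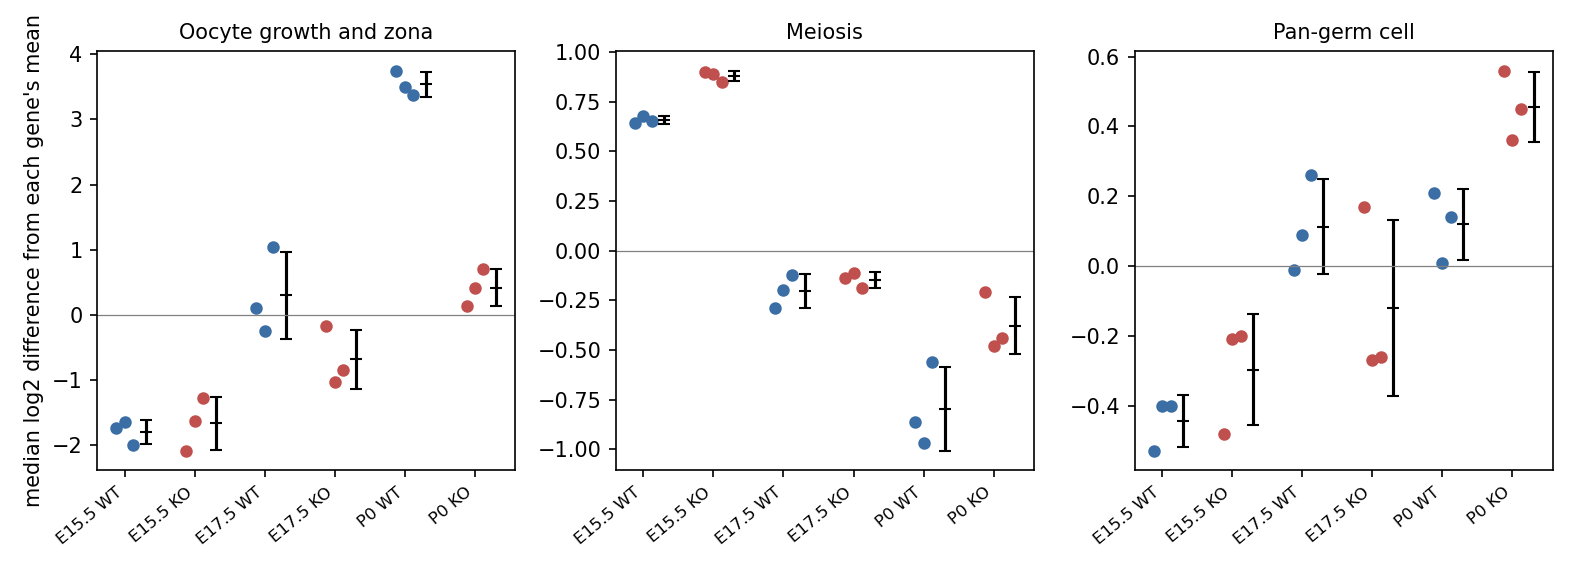
Median of the oocyte growth and zona, meiosis and pan-germ cell lists on each array, as log2 difference from each gene's mean over all arrays (vertical axes), by stage and genotype (horizontal axes). Points are arrays and black bars are the mean and SD of 3. The oocyte growth list lies between 3.37 and 3.75 in wild type at P0 and between 0.14 and 0.70 in knockout.

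Among the somatic lists at P0, the endothelial list held 20 genes, of which 12 rose, 1 fell and 7 did not pass the test (median log2 change 0.37, camera adjusted p = 0.000711; adjusted p = 0.477 with an estimated correlation), with the receptor gene Tie1 at 0.68 ± 0.09, Pecam1 at 0.60 ± 0.09 and Egfl7 at 0.74 ± 0.12. Of 24 stroma and mesenchyme genes, 8 rose, 0 fell and 16 did not pass the test (median log2 change 0.32, camera adjusted p = 0.00111; adjusted p = 0.477 with an estimated correlation), with vimentin (Vim) at 0.57 ± 0.08. Of 22 immediate early and stress genes, 10 rose, 0 fell and 12 did not pass the test (median log2 change 0.42, camera adjusted p = 0.00111; adjusted p = 0.477 with an estimated correlation), with Atf3 at 1.28 ± 0.26, Klf4 at 1.25 ± 0.26 and Jun at 0.54 ± 0.15. Cell division genes went down: 0 rose, 10 fell and 21 did not pass the test of 31 (median log2 change -0.30, camera adjusted p = 0.000711; adjusted p = 0.686 with an estimated correlation), including Ube2c at -0.95 ± 0.17, Bub1b at -0.54 ± 0.10 and E2f1 at -0.56 ± 0.10. Cholesterol synthesis genes also went down: 2 rose, 9 fell and 11 did not pass the test of 22 (median log2 change -0.16, camera adjusted p = 0.00835; adjusted p = 0.477 with an estimated correlation), with squalene synthase (Fdft1) at -1.51 ± 0.10, Fdps at -0.70 ± 0.09 and Sqle at -0.57 ± 0.07. Among 30 pregranulosa cell genes, 11 rose, 4 fell and 15 did not pass the test (camera adjusted p = 0.234): the transcription factor genes Lhx9 and Gata4 rose by 0.94 ± 0.14 and 0.94 ± 0.14, and Esr2, the estrogen receptor beta gene, changed by -0.93 ± 0.18. Of 17 Notch pathway genes, 5 rose, 4 fell and 8 did not pass the test (camera adjusted p = 0.678). The ligand gene Jag1 fell by 1.59 on the log2 scale and the target genes Hey1 and Hey2 changed by -1.04 and -1.32, whereas Hes5 rose by 1.62. In the Sertoli cell list, 4 rose, 9 fell and 8 did not pass the test (camera adjusted p = 0.114), with Tesc at -2.85 and Col9a3 at -1.79. In the surface epithelium list, 8 rose, 1 fell and 5 did not pass the test (camera adjusted p = 0.052), with the keratin gene Krt18 at 0.55 and Cdh1, E-cadherin, at -0.83. In the p53 and apoptosis list, 5 rose, 2 fell and 23 did not pass the test (camera adjusted p = 0.595), with Pmaip1 at 1.46 ± 0.14 and Trp53inp1 at 0.60 ± 0.06. Red cell genes had a median of -1.18, and limma called 0 of 16. The other lists that camera did not call had medians between -0.44 for the pluripotency list and 0.32 for the hedgehog pathway, with the Sertoli cell list at -0.33 and the ELAV family and oocyte transcription factors at -0.19 each. Median, mean and camera direction differed in sign for the steroidogenic, mesonephros, Notch and TGF-beta lists.

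Of the 7 list calls at P0, 0 held with an estimated correlation, and other splits of the 6 arrays called up to 8 lists. For 3 of the 7 no other split gave as low an adjusted p, the lowest being 1.28e-08 for oocyte growth, 0.00124 for endothelial and 0.011 for cholesterol synthesis genes. Other splits went lower for immediate early (3.15e-15), stroma (1.81e-06), cell division (8e-06) and meiosis genes (5.22e-05). Scaling by the array median moved the median change of all genes by 0.14 and gave 7139 calls, 73.3% of them higher in knockout against 53.1%, so the balance of rises and falls depended on the scaling.

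**Figure D3:**
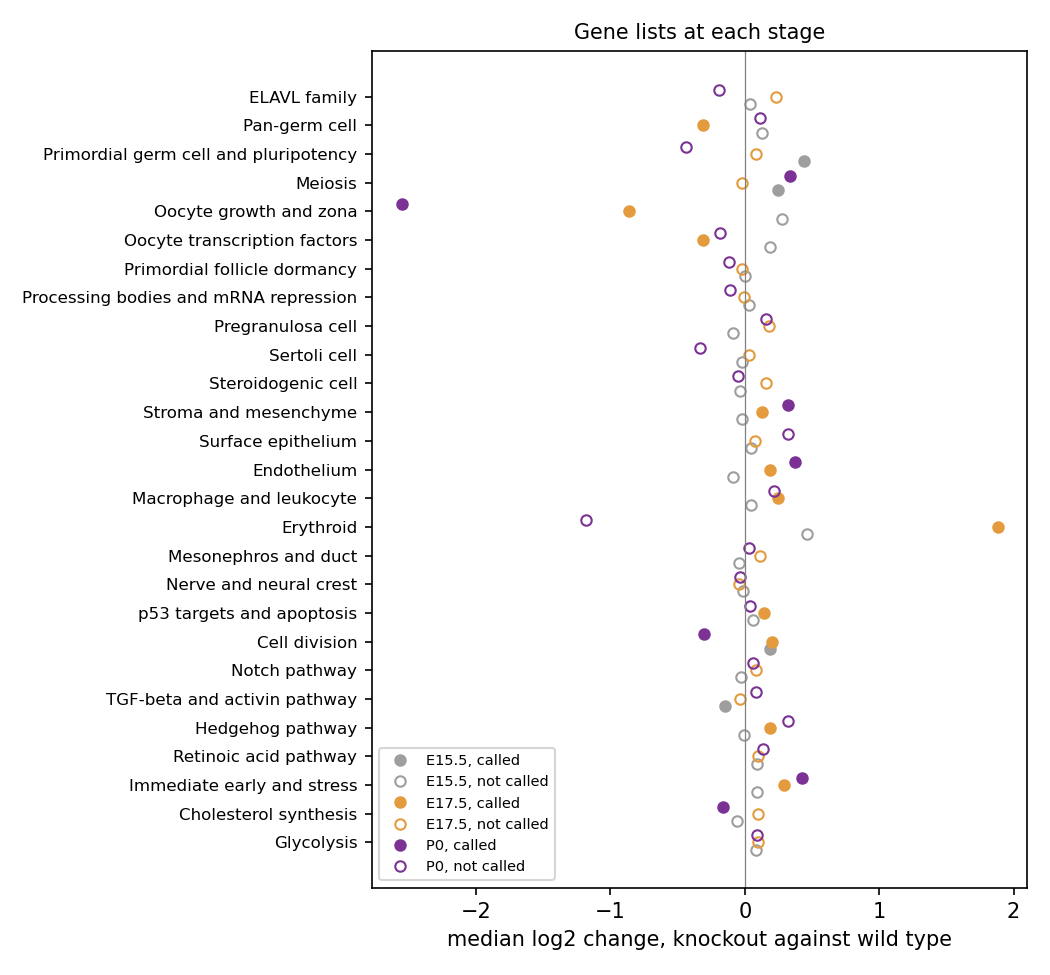
Median log2 change of the 27 tested gene lists (vertical axis) between knockout and wild type at each stage (horizontal axis, log2). Filled points are lists with a camera adjusted p under 0.05 at the preset correlation. The oocyte growth and zona list stands at -2.55 at P0, and the red cell list at 1.88 at E17.5.

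Over the mean of the 3 stages 4989 genes were called, 2715 higher and 2274 lower in knockout. Of 47 oocyte growth genes, 1 rose, 33 fell and 13 did not pass the test (median log2 change -1.20, camera adjusted p = 2.39e-15; adjusted p = 0.345 with an estimated correlation), and of 38 meiosis genes 16 rose, 2 fell and 20 did not pass the test (median log2 change 0.15, camera adjusted p = 0.00565; adjusted p = 0.548 with an estimated correlation). Camera also called 3 other lists up. Of 22 immediate early and stress genes, 9 rose, 0 fell and 13 did not pass the test (median log2 change 0.28, camera adjusted p = 0.000395; adjusted p = 0.548 with an estimated correlation). Of 24 stroma genes, 7 rose, 0 fell and 17 did not pass the test (median log2 change 0.15, camera adjusted p = 0.0082; adjusted p = 0.548 with an estimated correlation), and of 20 endothelial genes 9 rose, 0 fell and 11 did not pass the test (median log2 change 0.18, camera adjusted p = 0.00842; adjusted p = 0.548 with an estimated correlation). Genes called in the same direction at all 3 stages numbered 39, and 29 of these were lower. The call sets of different stages overlapped more than independent sets of the same size: 47 genes were lower at both E15.5 and E17.5 against 3.52 expected (Fisher's exact test, p = 1.69e-40), and 363 at both E17.5 and P0 against 87.9 (p = 9.86e-160). For higher genes the counts were 15 against 2.49 (Fisher's exact test, p = 3.27e-08) and 161 against 47.1 (p = 2.53e-56). E15.5 and P0 shared 61 higher genes against 34.2 (Fisher's exact test, p = 2.34e-06) and 48 lower genes against 20.2 (p = 1.88e-09). In opposite directions, 39 genes were higher at E15.5 and lower at P0, and 10 were lower at E15.5 and higher at P0. These opposite counts were not tested against an expected number. With median scaling, 38 higher genes were shared by E15.5 and P0 (Fisher's exact test, p = 0.259), which ended that call. The stages shared no array, but all calls used 1 estimate of each gene's spread, so a gene with a small spread is called more easily at every stage. Slide 3 held arrays of E15.5 and E17.5, and slide 4 arrays of E17.5 and P0. Genes are also not independent replicates, so these p-values do not measure an effect shared between stages.

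Whether the knockout effect differed between stages was tested with limma on the difference itself. Chance was not excluded for any of the counts that follow, as set out below. At E15.5 and P0 all wild type arrays shared a slide with no knockout array, so a slide difference cannot be told apart there. From E15.5 to E17.5 the knockout effect differed for 59 genes by this test. The difference (the later log2 change minus the earlier) was positive for 7 and negative for 52. The difference was -2.82 (SE 0.37, adjusted p = 0.0197) for Fgf21, -2.14 (SE 0.36, adjusted p = 0.0391) for Esrrb and -2.78 ± 0.46 for Cldn16. It was 3.23 ± 0.52 for Usp17lb, 1.51 ± 0.26 for the serotonin receptor gene Htr5a and 1.16 ± 0.21 for Hoxd3, whose probes disagreed. From E17.5 to P0 it differed for 2010 genes, 824 and 1186, and from E15.5 to P0 for 3852, 1838 and 2014. Of the genes with a difference given here, Elavl2, Esrrb, Hoxd3 and Nkx2-4 were well above background on some array of every group involved. The other differences rest in part on measured dim signals and are not bounds. From E17.5 to P0 the difference was -5.38 (SE 0.26, adjusted p = 4.83e-07) for Oosp1, -4.88 ± 0.85 for Astl and -4.58 ± 0.71 for Khdc1a. It was 2.69 (SE 0.32, adjusted p = 0.00057) for Wnt3 and 2.39 ± 0.36 for Nkx2-4, whose probes disagreed. Between E15.5 and P0 the difference was -6.10 ± 0.85 for Astl, -5.58 ± 0.26 for Oosp1, -5.16 ± 0.55 for Zp1, 4.05 ± 0.55 for Insm1 and 3.12 ± 0.32 for Wnt3. For Elavl2 it was -1.25 (SE 0.17, adjusted p = 0.000651) from E15.5 to P0, while the steps -0.76 ± 0.17 and -0.49 ± 0.17 did not pass the test (adjusted p = 0.0994 and 0.0878). The 59 genes rested on single arrays: limma called 0 without E15.5 wild type 1, E15.5 knockout 2 or E17.5 wild type 1 (1877, 2396 and 2205 at an unadjusted p under 0.05), 1 to 11 without any other E15.5 or E17.5 array except knockout 1 of either stage, and 263 without E17.5 knockout 1. Without slide 3 it was 39 genes, 28 of them with a positive difference, and 9 were shared with the 59. With median scaling the shares with a positive difference were 26.3%, 68.6% and 72.9% against 11.9%, 41.0% and 47.7%, and without P0 wild type 2 the later differences gave 1047 and 2560 genes. The difference between E17.5 and P0 gave 1222 genes without E17.5 knockout 2, 1328 without knockout 3, 1335 without wild type 2 and 1336 without wild type 3.

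In wild type the oocyte growth list went up and the meiosis list down at both steps, by camera with the preset correlation. From E15.5 to E17.5, 5090 genes were called, 2953 higher and 2137 lower. Nlrp5 was at least 31.7-fold higher, the oocyte gene Trim61 at least 51.4-fold, Olah at least 26.7-fold and Bcl2l10, of the BCL2 family, at least 16.2-fold. The scaffold protein gene Pdzk1 rose by 6.98 ± 0.52 and Dppa3 (Stella) by 5.81 ± 0.50. Stra8 changed by -7.70 (SE 0.53, adjusted p = 3.27e-06), and the embryonic globin genes Hba-x and Hbb-y by -4.92 ± 0.64 and -4.56 ± 0.68. The nuclear receptor gene Hnf4a was at least 3.03-fold lower. Of 47 oocyte growth genes, 32 rose, 3 fell and 12 did not pass the test (median log2 change 2.57, camera adjusted p = 3.52e-11; adjusted p = 0.475 with an estimated correlation). Of 38 meiosis genes, 3 rose, 25 fell and 10 did not pass the test (median log2 change -0.77, camera adjusted p = 3.52e-11; adjusted p = 0.427 with an estimated correlation), with Iho1, Msh5 and Hormad2 at -2.94, -2.59 and -1.52. Of 11 oocyte transcription factor genes, 5 rose, 0 fell and 6 did not pass the test (median log2 change 0.56, camera adjusted p = 0.0205; adjusted p = 0.596 with an estimated correlation), with Nobox, Lhx8 and Figla at 4.89 ± 0.46, 4.31 ± 0.48 and 1.97 ± 0.25. That call ended without E17.5 wild type 3 (median 0.22, adjusted p = 0.238) and with the stricter filter (adjusted p = 0.0659). Of 22 cholesterol synthesis genes, 2 rose, 12 fell and 8 did not pass the test (median log2 change -0.39, camera adjusted p = 0.000916; adjusted p = 0.427 with an estimated correlation), with Tm7sf2, Dhcr7 and Msmo1 at -0.92, -0.49 and -0.63 but Fdft1 at 1.03. Of 21 macrophage and leukocyte genes, 7 rose, 0 fell and 14 did not pass the test (median log2 change 0.42, camera adjusted p = 0.0252; adjusted p = 0.778 with an estimated correlation), including Ptprc at 1.26 and Lyz2 at 2.43. That call ended without E15.5 wild type 1 (median 0.38, adjusted p = 0.0902) and with the replicate block (adjusted p = 0.0505). Elavl2 rose by 1.09 (SE 0.15, adjusted p = 0.000321). Without the run term 2494 genes were higher and 2670 lower, and 3406 of these were among the 5090. Without E17.5 wild type 3, the array of that group in run A, 1048 genes were called, 475 higher and 573 lower, and Hbb-y gave -2.79 and was not called (adjusted p = 0.0722). Median scaling shifted the median change by -0.21 and made 28.0% of calls higher against 58.0%.

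From E17.5 to P0 in wild type, 8352 genes were called, 4272 higher and 4080 lower. Khdc1a was at least 23.7-fold higher and Oosp1 at least 12.6-fold. Zp3 rose by 5.99 (SE 0.44, adjusted p = 1.81e-06), Zp1 by 5.79 ± 0.41, Nlrp14 by 5.99 ± 0.71, Astl by 5.89 ± 0.64, Zar1 by 5.81 ± 0.38 and Npm2 by 4.66 ± 0.23. The melanin synthesis gene Dct changed by -2.80 ± 0.49, Pdilt was at least 1.93-fold lower and Hba-x at least 1.66-fold lower. Of 47 oocyte growth genes, 41 rose, 1 fell and 5 did not pass the test (median log2 change 3.35, camera adjusted p = 4.93e-17; adjusted p = 0.521 with an estimated correlation). Of 38 meiosis genes, 3 rose, 24 fell and 11 did not pass the test (median log2 change -0.50, camera adjusted p = 3.06e-05; adjusted p = 0.521 with an estimated correlation), with Msh4, Spo11 and Mei1 at -1.47, -1.82 and -1.30. Of 18 primordial germ cell and pluripotency genes, 9 rose, 1 fell and 8 did not pass the test (median log2 change 0.70, camera adjusted p = 0.0229; adjusted p = 0.521 with an estimated correlation), including Pou5f1, Tfap2c and Lin28a at 3.43 ± 0.46, 2.51 ± 0.34 and 3.25 ± 0.51. Of 20 endothelial genes, 1 rose, 8 fell and 11 did not pass the test (median log2 change -0.25, camera adjusted p = 0.014; adjusted p = 0.596 with an estimated correlation), with Icam2 and Pecam1 at -0.80 and -0.59 but Cldn5 at 0.73. Of 20 glycolysis genes, 2 rose, 13 fell and 5 did not pass the test (median log2 change -0.56, camera adjusted p = 0.00342; adjusted p = 0.634 with an estimated correlation), with Hk2, Ldha and Eno1 at -1.75, -1.07 and -0.87. Of 22 cholesterol synthesis genes, 11 rose, 2 fell and 9 did not pass the test (camera adjusted p = 0.0857), with Fdft1 at 1.09 and Lss at 0.53. The probes of Lss disagreed, and their mean gave -0.14. Elavl2 rose by 0.86 (SE 0.13, adjusted p = 0.000264). Median scaling shifted the median change by -0.16 and made 31.4% of calls higher against 51.1%.

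The genes that changed in wild type between E15.5 and E17.5 were followed in the P0 comparison of genotypes, which uses other arrays. The 2953 that rose had a median log2 change of -0.22 in knockout at P0, with 933 lower and 338 higher (camera p = 1.28e-06; p = 0.177 with an estimated correlation). The 2137 that fell had a median of 0.09, with 558 higher and 299 lower (camera p = 0.0141; p = 0.304 with an estimated correlation). Across genes the changes correlated with Pearson's r = -0.26 and Spearman's rho = -0.21; genes are not independent replicates. The run term was set by E17.5 alone, whose run A arrays both lay on slide 3. The fitted wild type change therefore carries any deviation of that slide. Without the run term r was -0.08, and the median of the 2494 genes that rose was -0.03. Of these, 404 were higher and 576 lower at P0, and camera no longer called them. The 2670 that fell had a median of 0.08, with 564 higher and 303 lower. With median scaling 1600 genes rose and 4116 fell in wild type. At P0, 163 of the first were higher and 493 lower, and 1677 of the second higher and 241 lower (median 0.245).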

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

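The tests of a slide effect on the oocyte genes and of another tissue on slide 3 were set before their result was seen; those of other splits, fewer germ cells, later maturation and the shared deviation on slide 3, and the counts without slide 3, were chosen after. Results are given here because the effect of the knockout differed between stages by a test of the difference itself. It differed for 59 genes between E15.5 and E17.5, 2010 between E17.5 and P0, and 3852 between E15.5 and P0. Between E15.5 and E17.5 the differences were 4.50 for Olfr922, 3.23 for Usp17lb, 2.52 for Cdh12, 1.51 for Htr5a, 1.38 for Olfr1030, 1.16 for Hoxd3, -2.82 for Fgf21, -2.78 for Cldn16, -2.30 for Ccdc60, -2.23 for Umodl1, -2.14 for Esrrb and -1.78 for Lctl. Between E17.5 and P0 they were 2.69 for Wnt3, 2.40 for Cbln2, 2.39 for Nkx2-4, 2.38 for Pax6, 2.36 for Ankrd34b, 2.12 for Sox2, -5.38 for Oosp1, -4.88 for Astl, -4.87 for Gtsf1l, -4.72 for Ifi207, -4.58 for Khdc1a and -4.54 for Eya4. Between E15.5 and P0 they were -1.25 for Elavl2, 4.05 for Insm1, 3.98 for Gpr174, 3.63 for Olfr206, 3.33 for Nkx2-4, 3.15 for Slc22a13, 3.12 for Wnt3, -6.10 for Astl, -5.92 for Ifi207, -5.58 for Oosp1, -5.28 for Fpr-rs3, -5.16 for Zp1 and -5.10 for Oas1d. Other probes of Hoxd3, Nkx2-4, Cbln2 and Pax6 went the other way. Elavl2, Olfr1030, Hoxd3, Esrrb, Lctl, Cbln2, Nkx2-4, Ankrd34b, Slc22a13 and Oas1d were well above background on some array of every group involved. The other genes were below it in at least 1 of the 4 groups, and Sox2 in all 4, so their differences rest on dim signals and are neither bounds nor exact sizes.

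Other splits of the arrays were counted for each result. For a comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real split called 312, 801 and 6651 genes at E15.5, E17.5 and P0, and 5090 and 8352 between wild type stages, with at most 5, 6, 1, 1 and 5 genes in the other splits; the real split was in each case the 1 with as many. For gene lists the real numbers were 4, 11, 7, 5 and 5, the highest others were 9, 8, 8, 9 and 10, and 6, 1, 3, 5 and 8 splits called as many. Of 100 drawn splits, 1 gave as many genes for the mean of the stages (4989, highest other 1986). It was 1 for the difference between E15.5 and E17.5 (59, highest other 42) and 2 for that between E15.5 and P0 (3852, highest other 4151). The count for the mean carries the P0 effect: with P0 mixed the highest was 1. The few other splits that left P0 parted by genotype called 153 to 1986 genes, so chance is left open for the mean. The count between E15.5 and P0 carries the P0 effect itself: splits that mixed E15.5 and left P0 parted by genotype called 2544 to 3482 genes, and with P0 mixed the highest was 11, so chance is left open for that difference. For the 59 it stays open despite the count: with the replicate block 1 gene was called, and limma called 0 without E15.5 wild type 1, E15.5 knockout 2 or E17.5 wild type 1 (1877, 2396 and 2205 at an unadjusted p under 0.05). For the difference between E17.5 and P0, 7 of 100 gave as many (2010, highest other 6081), and chance is not excluded by that count. The 6 other splits behind it left the P0 arrays parted by genotype and regrouped only E17.5, so they carry the P0 effect itself. With the P0 arrays mixed, the highest count was 7.

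The first pattern is the fall of 38 of 47 oocyte growth and zona genes at P0. Fewer germ cells alone would lower all germ cell markers by about as much. Yet 22 pan-germ cell markers outside the list had a median change of 0.129 against -2.55, which argues against that as the whole cause. The 95% bootstrap interval, -0.24 to 0.58, was drawn over these genes and not over samples. Of the 23 pan-germ cell genes, 10 rose and 3 fell in wild type from E15.5 to E17.5. From E17.5 to P0, 5 rose and 3 fell. Signals of whole ovaries do not part the number of cells from the level per cell, so a partial loss is not excluded. A slide effect stays open: the list's median differed between slides within a group by 0.978 in E17.5 wild type, -0.354 in E17.5 knockout, 0.305 in E15.5 knockout and 0.483 in P0 knockout, where both E17.5 values are also differences of run. Within slide 3 the list's median change at E17.5 was -1.79, but the P0 wild type slide held no knockout. A later maturation of the knockout ovaries is a candidate explanation: of 2099 genes called in both comparisons, the list left out, 69.7% went at P0 against their change in wild type from E15.5 to E17.5. Without the run term the share was 61.2% of 1820. The run term was set by E17.5 alone, whose run A arrays both lay on slide 3. The fitted wild type change therefore carries that slide's deviation. As measured at E15.5, that deviation itself correlated with the P0 knockout effect at r = -0.247 across genes. The share thus cannot tell a later maturation from a slide difference.

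The second pattern is that the 3 arrays of slide 3 stood apart from the other arrays of their groups. They lay at 45.3, 23.9 and 47.4 on the second principal component (15.1% of the variance), and the others between -37.6 and -0.4. That position was not particular to slide 3: the P0 wild type arrays, on slide 6, lay at 39.6, 44.3 and 32.1. The P0 knockout arrays lay at -37.4, -24.1 and -28.1, so the same component also parted the genotypes at P0. Across genes, the deviation of the slide 3 array among E15.5 knockouts correlated with that of replicate 3 at E17.5 (r = 0.547), so a slide effect may be present; at E17.5 the slide is also the run. More of 1 somatic tissue common to those arrays is argued against: the largest median that any of 10 cell type lists shared between both deviations was 0.14. Germ cell lists were not among the 10. Their medians at E15.5 and E17.5 were 0.31 and 0.20 for oocyte growth, 0.19 and 0.45 for pluripotency and 0.29 and 0.12 for oocyte transcription factors. They were 0.08 and -0.07 for pan-germ cell and 0.09 and 0.09 for meiosis genes. A shared difference in germ cell content was not tested. The test of the 10 lists averaged the E17.5 wild type and knockout deviations, so it does not see tissue that differed between the arrays. Red cell genes stood at 3.2 on E17.5 knockout 3 and at -1.56 on wild type 3, which cancel in part. Tissue content particular to single arrays was not tested. The same E15.5 deviation correlated with the knockout effect at P0 at r = -0.247, and at -0.372 with the E15.5 effect of the other 2 knockout arrays, which enter both sides with opposite sign. The design gives no biological group for these 3 arrays, and a difference between the samples themselves was not tested further. Without slide 3, 259 genes were called at E15.5, 193 at E17.5 and 7636 at P0, of which 135, 152 and 6498 were among those called with it. That leaves the E17.5 wild type on slide 4 and the E17.5 knockout on slide 5, so these counts are not free of slide differences. At E15.5 the split of 187 higher and 125 lower became 99 and 160.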

How the results depend on the processing

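Leaving out slide 3, run B alone and the slide as a fixed block were chosen after seeing the data. Most values kept their direction, with fewer calls kept: of the named genes called, 92 of 116 at P0, 0 of 51 at E17.5 and 0 of 29 at E15.5 kept their call under all alternatives, as did 36 of 97 in wild type from E15.5 to E17.5 and 80.4% from E17.5 to P0. The mean of the probes reversed Elavl1 at E17.5 (-0.041) and P0 (-0.034) and Lss (-0.137) in wild type from E17.5 to P0. Normexp reversed Tsc1 at P0 (0.145). The slide as a fixed block, at E17.5 in effect 1 array against 1 on slide 3, reversed the stroma list there (-0.055). Where a cause is not given, the cause was not tested. Signal over background limits dim genes, whose folds between groups are bounds, while their differences between stages are fitted to dim signals.

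Called genes at E15.5 (312) became 40 without the run term, 935 with array weights, 144 with the slide as a random block and 0 (limma; 2894 at an unadjusted p under 0.05) with E15.5 arrays only, and leaving out arrays gave 23 to 471. At E17.5 (801) they became 385 with median scaling, 464 without a filter, 349 without the run term, 162 with array weights, 1 with E17.5 arrays only, 193 without slide 3 and 154 in run B alone, and 141 to 1032 without an array. For the difference between E15.5 and E17.5 (59) the counts were 99 with normexp, 19 with median scaling, 5 without a filter, 11 without the run term, 19 with array weights, 10 with the slide as a random block, 5 with only these stages, 39 without slide 3, and 0 to 263 without an array. Between E17.5 and P0 (2010) they were 1028 without the run term, 1040 with array weights and 1047 to 2026 without an array, and between E15.5 and P0 (3852) 2364 without the run term and 2560 to 3829 without an array. In wild type, E17.5 against E15.5 gave 1048 to 4657 and P0 against E17.5 6180 to 8079 without an array; P0 between genotypes gave 4797 to 6374 and the mean of the stages 4022 to 5197. A 2-fold threshold, which by construction calls fewer, left 52, 100 and 1222 genes at E15.5, E17.5 and P0, 213 for the mean, 31, 720 and 1185 for the differences in the order above, and 1688 and 2093 in wild type.

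Whether the replicate numbers pair the samples at E15.5 and P0 is not settled. Deviations of same-numbered arrays correlated weakly there, at -0.12 to 0.20 and 0.08 to 0.15. At P0 every wild type array correlated best with the knockout array of its own number, while at E15.5 and E17.5 not every one did. The replicate block called 19 genes at E15.5, 167 at E17.5 and 5691 at P0, and 1, 1061 and 2636 for the differences; it costs degrees of freedom.

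With an estimated correlation 0 lists were called in each of the 5 comparisons (3, 2, 1, 2 and 1 at an unadjusted p under 0.05). Fry, which tests another hypothesis, called 4, 1, 15, 12 and 14. Quantile normalization called 8 lists for wild type P0 against E17.5. At E17.5, 4 lists were called without slide 3, 6 in run B alone, 6 without either replicate 3 and 7 without knockout 2. Leaving out an array gave 6 to 12 lists there, and 3 to 5, 7 to 9, 4 to 6 and 5 to 6 in the other comparisons.

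Shared calls between stages moved with the filter and the scaling. Without a filter E15.5 and E17.5 shared 9 higher and 29 lower genes, E17.5 and P0 57 and 232, and E15.5 and P0 27 and 29. With median scaling E17.5 and P0 shared 50 and 177, and E15.5 and P0 38 (Fisher's exact test, p = 0.259) and 30. The stricter filter gave 27 higher genes for E15.5 and E17.5. Without the run term the genes that rose in wild type had a median of -0.029 at P0.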

Other observations

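In this part the test of linked variants was chosen after the result was seen, and the test of single probes before, though the excess near Elavl2 was itself noticed in these data. Genes near Elavl2 were called more often than genes elsewhere. Of 183 measured genes within 20 Mb of it on chromosome 4, 15 were called at E15.5 against 2.9 expected (Fisher's exact test, p = 2.4e-07), 18 at E17.5 against 7.6 (p = 0.0011) and 78 at P0 against 63.0 (p = 0.023). They include Cdkn2a, Hacd4, Snapc3 and Hspb11, and were named after their values were seen. Hacd4, an enzyme gene of fatty acid elongation, changed by 0.64, 0.81 and 0.70 at E15.5, E17.5 and P0. Of the 38 genes with a position that were called in the same direction at all 3 stages, 9 lay on chromosome 4 against 2.36 expected (Fisher's exact test, p = 0.000423). Of those elsewhere, Dicer1, which makes microRNAs, gave -0.77, -0.92 and -0.84, and the centrosome genes Pcm1 and Cep290 gave -0.72, -0.67 and -0.56, and -0.71, -0.71 and -0.63.

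Strain variants carried along with the targeted gene are a candidate explanation, and they might hold an effect in 1 direction at all stages. Of the 15 near genes called at E15.5, 66.7% kept their direction at both other stages against 51.9% of 285 elsewhere (Fisher's exact test, p = 0.3), which leaves it open. Variants under single probes would make probes of a gene disagree: 33.3% of 6 near genes with several probes did, against 26.8% of 123 elsewhere (Fisher's exact test, p = 0.662), too few to decide. A direct effect of the knockout on these genes was not tested.

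Red cell genes varied between arrays of a group. Their median stood at 3.45, 0.35 and 0.84 in E15.5 knockout replicates 1, 2 and 3, at 1.01, -0.53 and -1.56 in E17.5 wild type, and at -2.09, 0.99 and -2.25 in P0 wild type. Only Zfy1 and Zfy2 of the Y-linked list were measured, and neither was called at any stage.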
